A study of Mus musculus with 13 samples.

How the data were processed

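Lin28A ChIP-seq, capture of 5-hydroxymethylcytosine (5hmC) and capture of 5-methylcytosine (5mC) were analysed in E14 cells, a mouse embryonic stem cell line, which per the labels' protocols was grown on mouse embryonic fibroblast feeders. Of 13 samples, 11 had a file used here: 1 input, 2 Lin28A ChIP replicates, 1 scramble and 1 knockdown library of 5hmC, 2 scramble and 2 knockdown libraries of 5mC, and 1 control and 1 triptolide library of Lin28A ChIP. The 2 RNA-seq samples and the authors' own peak list were not analysed here. Per the labels' protocols, chromatin carrying Lin28A was precipitated with a FLAG antibody. 5hmC was tagged with biotin through a glucosyltransferase reaction and pulled down on streptavidin beads, and 5mC was pulled down with an antibody. The knockdown used lentiviral short hairpins against Lin28A under puromycin selection, with a scramble hairpin as control.

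The deposited files hold counts per mapped position: each row is 1 distinct 37 bp interval on 1 strand with the whole number of reads that mapped there, and no position and strand occurred in more than 1 row of any file. The authors deposited 1 file per library, so replicates were not pooled. The aligner, the genome build and the filters of these libraries are not given in the sources used here. Per the submitters' processing notes the tools were TopHat2 2.0.8 and Cuffdiff 2.2.1, whose role for these libraries is not stated. Mapped reads passed the end of the last annotated gene of GRCm38 on 10 of 20 chromosomes, for example 197195277 against 195291439 on chromosome 1, so the coordinates belong to another build, and their extent fits the older mouse build NCBI37 (mm9). That build is inferred, not stated. The gene tables at hand are of GRCm38.p6, so no gene was assigned to any region. Comparisons of promoters, of the 16 gene lists fixed in advance and of GC content were not run, and regions are named by coordinates, 1-based.

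Each read was placed 100 bp downstream of its 5′ end, which is near the middle of the selected fragments, and counted in 1 kb bins over chromosomes 1 to 19 and X (2638956 bins). The 3059 bins with more than 5 times the median input count of 5 reads were left out as repeat artefacts. They held 1.27% of input reads. Counts were scaled to each library's total over these chromosomes (CPM). A bin was called bound when a one-sided exact binomial test of ChIP against input gave a Benjamini-Hochberg adjusted p under 0.01 and the CPM was at least 2 times that of input, in both ChIP replicates. The same rule, per library, defined bins above input for 5hmC and 5mC. Unbound bins were those with input reads that neither replicate called (2160363 bins). Tests against the single input compare libraries, not conditions.

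For 5mC, with 2 libraries on each side, edgeR's quasi-likelihood test was fitted to bins with a mean CPM of at least 1, with library totals as the scale, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design written in advance named limma on log2(CPM + 0.5), because the files were not known to hold counts. The test was changed to fit the unit, and limma is given as an alternative. At bound bins, the mean log2(CPM + 0.5) difference between knockdown and scramble was compared with unbound bins in 10 strata of scramble 5mC, and limma's camera was run with a preset correlation of 0.01 and with an estimated one. fry was run beside it and tests the bound bins against no change, without unbound bins. An exact permutation of 2 against 2 libraries cannot give a p below 0.333. For 5hmC and triptolide, with 1 library per condition, no test was made. The median log2 ratio of (CPM + 0.5) over bound bins was set beside 10000 random lists of unbound bins, matched in 10 strata on 5hmC signal or on input count. Intervals of medians come from 1000 bootstrap draws of bins. Ratios of summed reads and of single bins carry exact 95% binomial intervals of the unadjusted read ratio. Both kinds of interval cover counting error or the spread between bins only, not the spread between cultures, and reads without molecular identifiers are not independent molecules. The labels do not say whether replicates came from separate cultures, so the 5mC p-values of edgeR, limma, DESeq2 and fry measure only the spread between these libraries, which may be technical. Camera sets bound against unbound bins, so its p-values also depend on the spread across bins and on the correlation used. Binomial p-values cover the counting of reads or of bins only.

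The regions named were chosen by a rule set before the data were examined: the 10 bound bins with the highest mean log2 ratio over input; for 5mC the largest changes that passed the test, or the 5 smallest p-values if none did; and for 5hmC and triptolide the 5 highest and 5 lowest log2 ratios among bins with at least 100 reads over both libraries. The alternatives tried were 1 read per position, 2 kb bins, scaling by the median ratio over 10 kb bins, a pseudocount of 0.1, a 4-fold rule for bound bins, input artefacts kept, no filter on 5mC counts, a log2 limit of 0.58 in place of 1 for 5hmC, the replicate number as a block, and each replicate left out. TMM scaling, limma, DESeq2, matching on input count and matching on the 10 nearest unbound bins were added after seeing the data.

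Total reads per library ran from 5931352 to 12518112. The steps were tested on simulated data. For Lin28A ChIP against input over 2638956 bins, the caller found 9 of 100 bins raised 4-fold and 80 of 100 raised 8-fold in both replicates, and called 0 others. For 5mC over 175265 bins, edgeR found 12 of 100 bins raised 4-fold in the knockdown and 67 of 100 raised 8-fold, with 7 false calls. For 5hmC over 1172 bound bins, a simulated log2 change of -0.5 was returned as -0.50 from summed reads and as -0.24 on the log2(CPM + 0.5) scale, which shrinks low bins, and a change of 0 as 0.02 and 0.01. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9.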

Results

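Lin28A is an RNA-binding protein of embryonic stem cells, known for blocking the maturation of let-7 microRNAs, and Tet1 is an enzyme that oxidises 5mC to 5hmC. The series asked whether Lin28A also sits on DNA and acts there with Tet1. The files hold Lin28A ChIP-seq in E14 mouse embryonic stem cells, 5hmC and 5mC capture after a scramble or a Lin28A hairpin, and Lin28A ChIP-seq with triptolide, a compound that blocks transcription initiation, or its control. The input library held 12254168 reads. The ChIP replicates held 9116213 and 11747685 reads, the 5hmC libraries 12518112 (scramble) and 11732312 (knockdown). The 5mC scramble libraries held 7167158 and 11613789 reads and the 5mC knockdown libraries 5931352 and 11468963. The drug control held 6384052 reads and the triptolide library 10056374. The level of Lin28A itself after the knockdown was not analysed here. Reads beyond the first at a position made up 26.8% of 5mC knockdown replicate 2 and between 1.58% and 11.1% of each other library.

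Where on DNA does Lin28A sit? Lin28A was enriched over input at 1172 bins of 1 kb in both ChIP replicates, in 1136 separate regions. Of these regions, 1100 were a single bin and 36 spanned 2 kb, so the sites were narrow. Over the bound bins the ChIP reads stood 9.53-fold (95% counting interval 9.34 to 9.73) and 7.87-fold (7.72 to 8.03) above input in replicates 1 and 2. The same libraries chose these bins, which raises both values. The signal was 1.89-fold and 1.75-fold in the bin upstream and 1.96-fold and 1.81-fold in the bin downstream, and at 2 kb upstream it had fallen to 1.14-fold and 1.02-fold. In total the bound bins took 0.851% and 0.703% of the ChIP reads.

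**Figure D1:**
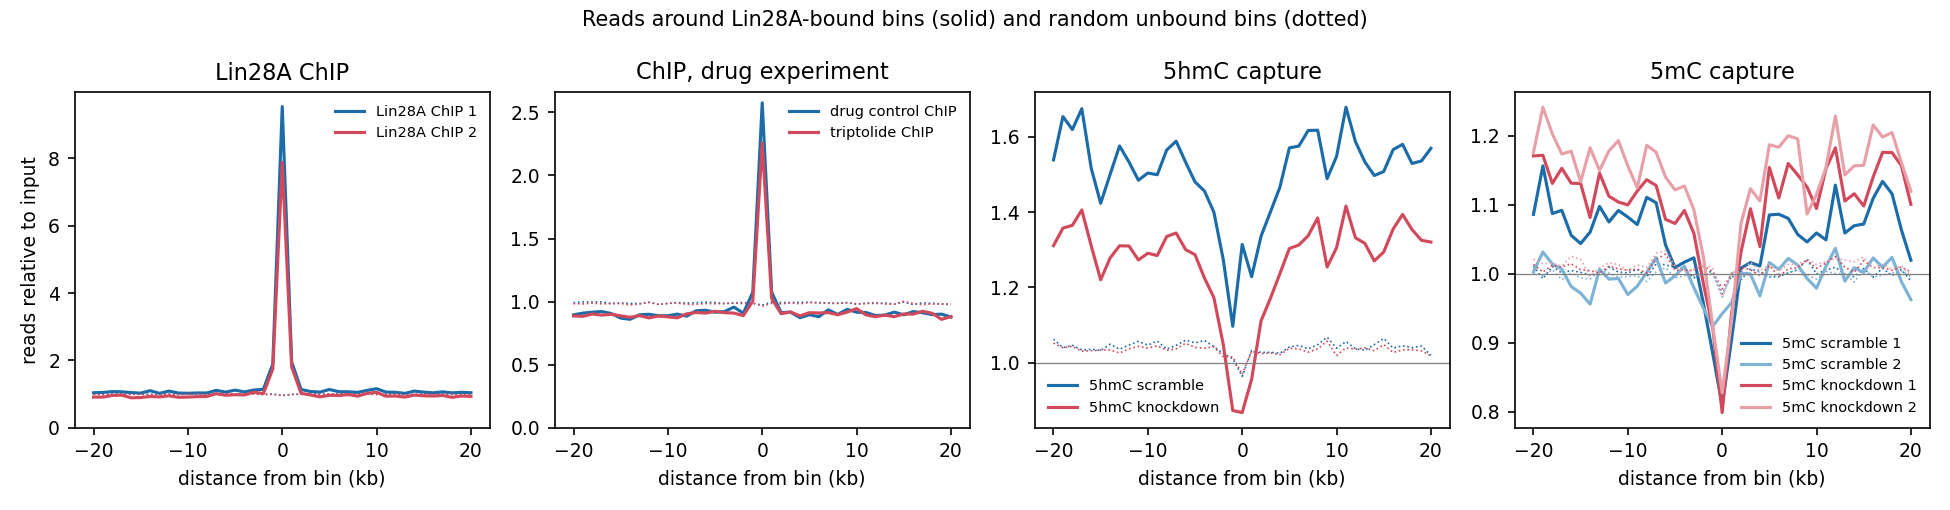
Reads relative to input (y axis, linear, a different range in each panel) against distance in kb from 1172 Lin28A-bound bins (solid lines) and from random unbound bins (dotted lines), for each library. The Lin28A ChIP peaks at 9.53 and 7.87 in the bound bin. The 5hmC scramble library reads 1.31 there and the knockdown library 0.867, and the 5mC libraries read between 0.798 and 0.942. Input is also higher in the bound bin, which lowers these ratios.

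Replicate 1 alone called 2112 bins and replicate 2 alone 1704, and 1172 were shared. Both lists were called against the same input, so they are not independent, and the values below share it too. No bin was called in the reverse direction, input over ChIP, in either replicate. Bins with high input had been left out as artefacts, however. With the input counts that remained, the reverse test could hardly reach the adjusted threshold. Its outcome therefore says nothing about how specific the ChIP calls are. In the 940 bins called by replicate 1 only, replicate 2 stood at 3.19-fold over input, and in the 532 called by replicate 2 only, replicate 1 stood at 3.51-fold. The bound bins also held more input reads than unbound ones (9.32 against 5.58 per bin). Input was the only control for the FLAG precipitation among the samples, with no mock or knockdown ChIP. Unspecific pull-down shared by both replicates was therefore not tested.

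Sites were ranked by the mean log2 ratio of (CPM + 0.5). The first lay on chromosome 4, 150978001 to 150979000 in the inferred NCBI37 coordinates, with 461 and 739 ChIP reads against 6 input reads. This is 103-fold (counting interval 47.1 to 283) and 129-fold (58.8 to 351) over input. The adjoining bin, starting at 150979001, was also bound. The bin on chromosome 15 from 72399001 to 72400000 followed, with 244 and 366 ChIP reads against 2 in input. Its mean log2 ratio was 5.47 ± 0.15 (SD, n = 2, which leaves out the error of the shared input). Its unadjusted folds were higher than those of the first site, at 164 (44.9 to 1362) and 191 (52.5 to 1583). Next came chromosome 14, 64300001 to 64301000 (5.38 ± 0.39), chromosome 18, 25826001 to 25827000 (5.37 ± 0.03), chromosome 7, 6362001 to 6363000 (5.23 ± 0.09), and chromosome 15, 77950001 to 77951000 (5.21 ± 0.41). The remaining bins of the first 10 were on chromosome 4, 139815001 to 139816000 (5.02 ± 0.54), chromosome 13, 55072001 to 55073000 (5.00 ± 0.46), chromosome 18, 82588001 to 82589000 (4.85 ± 0.24), and chromosome 19, 4989001 to 4990000 (4.84 ± 0.31). With 1 read per position these means were lower, for example 5.11 at the chromosome 4 site, since a position then counts once however many reads it holds.

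Bound bins were spread unevenly over the chromosomes. Chromosome 11 held 117 of them, 1.97 times its share of bins with input reads (adjusted p = 8.32e-11, two-sided exact binomial test, Benjamini-Hochberg over 20 chromosomes). Chromosomes 4, 5, 7 and 19 were also above their share, at 1.55, 1.38, 1.48 and 1.48 times. Chromosome X held 8 bound bins, 0.158 times its share (adjusted p = 1.78e-12), with 2.45 input reads per bin against 4.97 to 6.73 on the autosomes. Chromosomes 1, 3, 13 and 16 were below their share, at 0.656, 0.568, 0.517 and 0.597 times. The other 10 chromosomes did not differ past the threshold. Input coverage ran the same way on the autosomes, with 5.91 to 6.73 input reads per bin on the chromosomes above their share and 4.97 to 5.55 on those below, and the test does not correct for it. It also takes bins as independent, which neighbouring bins are not.

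Does 5hmC at these sites depend on Lin28A? In the scramble library the bound bins carried 1.31-fold the 5hmC reads of input (1.28 to 1.35), and in the knockdown library 0.867-fold (0.843 to 0.892). The input that selected the bound bins is also the denominator here, which tends to raise such ratios in every library. The summed 5hmC reads over bound bins were lower in the knockdown by 0.60 on the log2 scale (log2 ratio -0.60, counting interval -0.64 to -0.56), which is 0.66 of the scramble level. The 293 most weakly and the 293 most strongly bound bins gave -0.64 and -0.64, and the bins between gave -0.57 and -0.56. In the scramble library 93 of the 1172 bound bins were above input in 5hmC (7.94%, exact interval 6.45% to 9.63%), and in the knockdown library 20 were (1.71%, 1.05% to 2.62%), all 20 among the 93. The same shares over unbound bins were 3.70% and 2.18%.

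**Figure D2:**
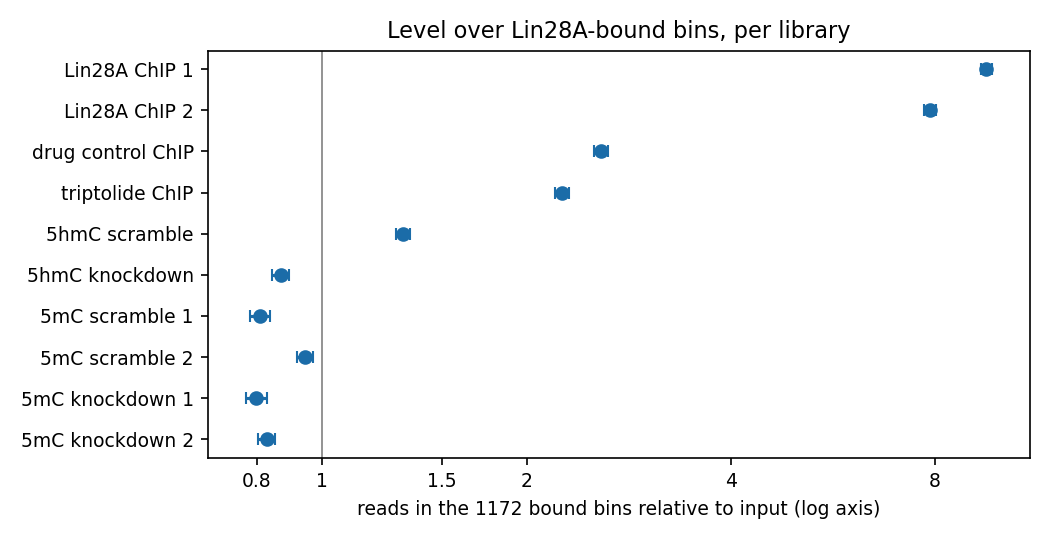
Reads over the 1172 Lin28A-bound bins relative to input (x axis, log scale) for each library, with exact 95% binomial intervals that cover counting error only. The 5hmC library reads 1.31 with scramble and 0.867 with knockdown, on either side of the input level, and the drug control reads 2.58 against 2.26 with triptolide.

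Per bin, the median log2 ratio of knockdown over scramble was -0.21 at bound bins (bootstrap interval -0.24 to -0.21) and 0.02 over matched lists of unbound bins, and 0 of 10000 such lists was as low. That bound median equals the value of a bin with 1 scramble and 0 knockdown reads, a tie that also sets the interval's upper end. With a pseudocount of 0.1 the bound median was -0.41, so its size depends on the pseudocount. In reads summed over the bins of a class, bound bins lay below unbound bins at each 5hmC level, for example at -0.65 against -0.19 between 1.5 and 2.5 CPM. The medians per bin in that class were -0.55 and -0.15, and under 0.1 CPM both were 0. Around the sites 5hmC was high in both libraries and also lower with knockdown: 10 kb upstream it stood at 1.504-fold over input with scramble and 1.29-fold with knockdown. At 10 kb upstream of random unbound bins 5hmC stood at 1.05-fold and 1.04-fold. In the bins next to the site it was 1.10-fold and 1.23-fold with scramble, so the bound bin stood above its neighbours there. With knockdown those bins were at 0.873-fold and 0.956-fold and the bound bin, relative to input, was not above them. Input was higher in the bound bin, at 0.762 CPM per bin against 0.671 and 0.660 in the bins next to it, which lowers the ratio there. The missing peak with knockdown may therefore come from the denominator. With 1 library per condition there is no replicate check of any of these values.

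**Figure D3:**
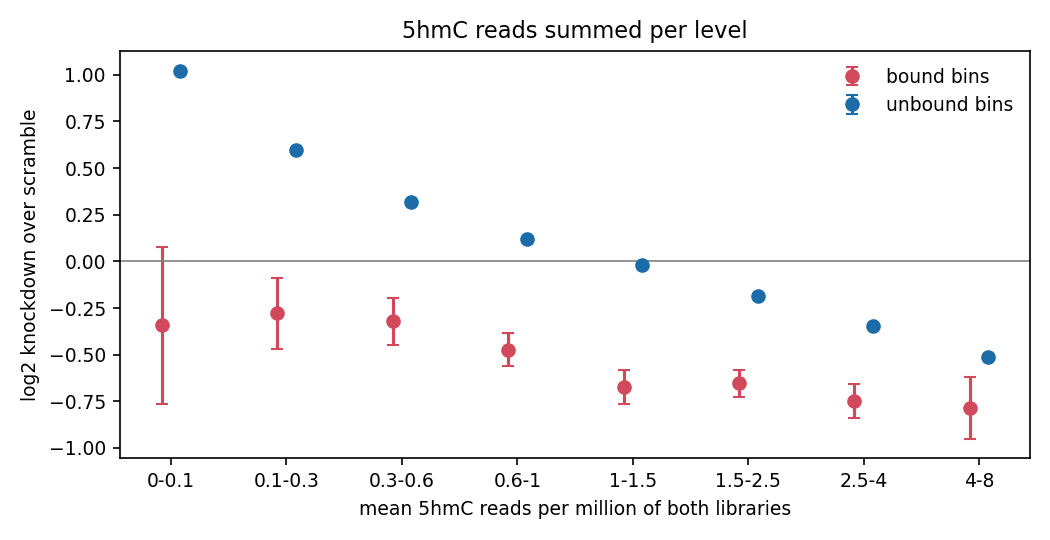
Log2 ratio of summed 5hmC reads, knockdown over scramble (y axis), in classes of mean 5hmC CPM of both libraries (x axis), for Lin28A-bound and unbound bins, with exact 95% binomial intervals that cover counting error only. Bound bins lie below unbound bins in every class, by -0.65 against -0.19 in the class from 1.5 to 2.5.

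Over the whole genome, 5hmC was less concentrated in the knockdown library. In the scramble library 80421 bins stood above input and held 31.3% of reads, and in the knockdown library 47575 did and held 16.0%, with 38103 bins in both. Of 18084 bins with at least 100 reads, 16902 had less 5hmC in the knockdown and 1182 more, with a median log2 ratio of -0.48. By the size rule, a log2 ratio beyond 1 with a counting interval outside 0, 24279 bins were higher in the knockdown and 13143 lower. Redrawing the same reads with no difference between the libraries gave 6028 and 5457. The higher bins held a median of 11 reads over both libraries and the lower ones 30. The split depended on the settings: 15718 higher and 15281 lower with scaling over 10 kb bins, 22568 and 5681 in 2 kb bins, and 33141 and 40390 with a log2 limit of 0.58, where the majority turned to lower.

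The lowest ratios among bins of at least 100 reads were on chromosome 7, 4945001 to 4946000 (119 reads with scramble, 26 with knockdown, log2 ratio -1.88, counting interval -2.77 to -1.48), and chromosome 7, 51609001 to 51610000 (123 and 32 reads, -1.68). Chromosome 2 from 164658001 to 164659000 (-1.66), chromosome 7 from 142602001 to 142603000 (-1.66) and chromosome 2 from 130997001 to 130998000 (-1.65) followed. The highest was on chromosome 7, 128389001 to 128390000, with 51 reads against 96 (0.92, interval 0.50 to 1.53). It was followed by chromosome 11 from 114498001 to 114499000 (0.83), chromosome 4 from 130308001 to 130309000 (0.83), chromosome 14 from 119053001 to 119054000 (0.74) and chromosome 5 from 123098001 to 123099000 (0.74). None of these 10 bins was bound by Lin28A.

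Did 5mC at the bound sites change with the knockdown? Relative to input, 5mC at bound bins stood at 0.809 and 0.942 in the scramble replicates and at 0.798 and 0.827 in the knockdown replicates. At 10 kb upstream the same libraries stood at 1.08, 0.970, 1.10 and 1.16. Input itself rose from 0.621 CPM per bin there to 0.762 in the bound bins, which lowers the ratio at bound bins. In scramble replicate 2 the adjoining bins stood at 0.924 and 0.958, so the bound bin was not below both. The scramble and knockdown ranges over bound bins overlapped. The mean log2 difference of knockdown and scramble at bound bins was -0.09, against -0.07 at unbound bins of the same 5mC level, a difference of -0.01. limma's camera gave p = 0.684 with a preset correlation and p = 0.836 with an estimated correlation. fry, which tests the bound bins against no change rather than against unbound bins, gave p = 0.364, where an exact permutation of these 4 libraries cannot go below 0.333.

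The direction of that difference was set by the scramble library used. Against scramble replicate 1 the bound bins moved by 0.08 and 0.10 more than matched unbound bins in knockdown replicates 1 and 2, and against scramble replicate 2 by -0.13 and -0.11. Without scramble replicate 1 the difference was -0.12 (camera p = 0.0318 with the preset correlation and p = 0.0846 with an estimated correlation). Without scramble replicate 2 it was 0.09 (p = 0.0825 and p = 0.104 with the same correlations). Scramble replicate 2 had 63 bins above input, against 2333 in scramble replicate 1 and 1564 and 12286 in the knockdown replicates.

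Genome-wide, none of 175265 bins tested differed in 5mC between knockdown and scramble at an adjusted p under 0.05 with edgeR's quasi-likelihood test, and 14077 bins had an unadjusted p under 0.05. limma called 0 bins and DESeq2 called 0. With TMM factors 9663 bins had such an unadjusted p with the same edgeR test. The median log2 fold change over the tested bins was 0.41 with scaling to library totals and 0.00 with TMM factors, so single values below include that shift. The 5 smallest p-values, none of which passed, were all higher in the knockdown. They were chromosome 15 from 37277001 to 37278000 (4 and 2 reads with scramble, 11 and 33 with knockdown, log2 fold change 2.85, adjusted p = 0.344), chromosome 8 from 14285001 to 14286000 (2.79), chromosome 11 from 118163001 to 118164000 (2.83), chromosome 6 from 145026001 to 145027000 (2.80) and chromosome 15 from 58681001 to 58682000 (2.79). Without scramble replicate 1, edgeR called 37 bins, 35 higher and 2 lower in the knockdown, with the lone scramble library assumed to vary like the knockdown ones. In that fit the median log2 fold change over all tested bins was 0.66, so the split between higher and lower calls carries little weight. The 2 lower bins, looked up after their values were seen, were on chromosome 7 from 97590001 to 97591000 and chromosome 2 from 164532001 to 164533000. At the first, scramble replicate 2 held 40 reads and scramble replicate 1 held 0, and at the second they held 77 and 6, with 6 and 10 in the knockdown replicates, so neither separated the groups. Tests at this depth found 67% of simulated 8-fold rises in the knockdown and 12% of 4-fold ones. Falls and smaller changes were not simulated. The simulated libraries shared 1 mean per bin before the rise, so the nearness of scramble replicate 2 to input was not reproduced.

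Does Lin28A binding need ongoing transcription? The ChIP signal at bound bins persisted in the triptolide library at a slightly lower level. It stood 2.26-fold over input (2.21 to 2.31) with triptolide and 2.58-fold (2.51 to 2.64) with its control. The log2 ratio of summed reads, triptolide over control, was -0.19 (counting interval -0.22 to -0.16), a fold of 0.876. Each drug library had 47 bins above input, all 47 of them bound in the first experiment and 37 common to both. In these 37 bins the control stood 9.83-fold and triptolide 8.72-fold over input. The triptolide library held more reads than the control (10056374 against 6384052), which eases calling, so equal counts of bins do not mean equal enrichment. Both drug libraries were less enriched at bound bins than the ChIP replicates of the first experiment. Those replicates chose the bins, which raises their values there, and the drug libraries did not.

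Per bin the median log2 ratio of triptolide over control was -0.14 (bootstrap interval -0.17 to -0.10), against 0.01 over unbound lists matched on input, and 0 of 10000 lists was as low. Unbound bins stood at 0.969 (control) and 0.967 (triptolide) of input, so such lists stay near 0 if the precipitation was weaker. They cannot tell weaker precipitation from reduced binding. With scaling over 10 kb bins the median was -0.09. Of 30 bins with at least 100 reads, all bound, 23 were lower and 7 higher with triptolide. The lowest were chromosome 7 from 25144001 to 25145000 (71 reads in control, 70 in triptolide, log2 ratio -0.64, counting interval -1.17 to -0.18), chromosome 4 from 150979001 to 150980000 (-0.56), chromosome 2 from 152858001 to 152859000 (-0.51), chromosome 11 from 55421001 to 55422000 (-0.51) and chromosome 9 from 21754001 to 21755000 (-0.51), and among these the interval of the chromosome 2 bin reached 0.02. The highest were chromosome 12 from 106560001 to 106561000 (0.38, interval -0.19 to 1.03), chromosome 14 from 64300001 to 64301000 (0.34), chromosome 4 from 139814001 to 139815000 (0.27), chromosome 4 from 150663001 to 150664000 (0.22) and chromosome 19 from 4989001 to 4990000 (0.21), and the counting interval of each of these included 0. The first-ranked site, at chromosome 4 from 150978001, held 113 reads in control and 170 with triptolide, a log2 ratio of -0.06. There was 1 library per condition and no replicate check.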

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

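The tests of weak capture, of ChIP reads and of input-like background in the 5hmC libraries, and of depth and of a wrong file in the 5mC libraries, were chosen only after the results they bear on were seen.

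Mitochondrial reads lie outside the chromosomes compared above. They made up 0.135% of Lin28A ChIP replicate 2, 0.107% of the drug control and 0.117% of the triptolide library, against 0.0671% of input. ChIP replicate 1 had 0.0677%, which overlaps the input interval of 0.0656% to 0.0685%. No biological explanation was tested.

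The loss of 5hmC at Lin28A-bound bins in the knockdown library is the pattern that bears most directly on the question of the series. Weaker capture alone, as a mixture of the scramble profile and input, would leave the bound bins between 1.31 and 1 relative to input. They stood at 0.867 (0.843 to 0.892), which argues against weaker capture only if background equals input at these bins. The 5mC libraries stood at 0.798 to 0.942 there, so weaker capture over a background below input cannot be excluded. Bins of the same kind falling alike is argued against by the 10 nearest unbound bins in input, 5mC, own 5hmC and flanking 5hmC, below which the bound bins lay by a mean log2 of -0.28 (bootstrap interval -0.30 to -0.25), or -0.51 in summed reads, and duplicate reads by -0.29 (-0.32 to -0.26) with 1 read per position. The nearest bins were matched on the level of flanking 5hmC, not on its change. Flanking 5hmC of bound bins also fell, from 1.504 to 1.29 relative to input at 10 kb upstream and from 1.54 to 1.31 at 20 kb. Random unbound bins stood at 1.05 and 1.04 at 10 kb. The excess therefore includes any fall shared with the surroundings. Stray Lin28A ChIP reads in the scramble library would make the extra 5hmC of the 293 most strongly bound bins 4.65 times that of the 293 most weakly bound, and it was 1.53 times (1.14 to 2.10). A loss of 5hmC at and around these sites with Lin28A may therefore be a hypothesis worth following. As a log2 ratio of summed reads the fall did not grow with the ChIP signal. It was -0.64 at the most weakly and -0.64 at the most strongly bound bins. Weaker capture over a background below input stays open. So do a sequence bias such as GC content that differs between the libraries, and chance differences between single cultures, which were not tested.

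In the flatter 5hmC profile of the knockdown library, mitochondrial reads rose from 0.000623% (0.000493% to 0.000778%, 78 reads) with scramble to 0.00157% (0.00135% to 0.00181%, 184 reads), the direction that more input-like DNA in the knockdown capture would give. The size argues against such DNA as the whole cause: the rise in chromosome X reads would need 18.2% of input and a mitochondrial share of 0.0127%, the fall at 18084 bins of at least 100 reads would need 37.4%, and the share seen allows 1.42%, or 4.74% at the lowest mitochondrial share of the 5mC libraries. Duplicate reads do not account for it either, since with 1 read per position the scramble library still had 1.64 times as many bins above input. What stays open is a small part from such DNA, a real change in 5hmC, which the knockdown design names, and a capture that favoured dense 5hmC less strongly, and the last 2 were not tested, with 1 library per condition.

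Scramble replicate 2 of 5mC lies close to input and sets the direction of the 5mC comparison at bound bins. It had 11613789 reads, more than each other 5mC library, and with 1 read per position the others still had at least 24.8 times as many bins above input, so depth and duplicates are argued against. At 1376 bins above input in both knockdown libraries it stood at 2.52 relative to input (2.47 to 2.57), against 5.96 in scramble replicate 1, the fair comparison since the knockdown values (6.65 and 8.75) are high by this choice of bins, which is consistent with a weak 5mC capture in that library. A wrong file under this label stays open: 2.52 lies within the range of the other libraries, at 0.695 of the highest, although the ChIP and drug libraries reached at most 1.16 and the 5hmC libraries, at 3.62 and 3.11, held far fewer mitochondrial reads (at most 0.00157% against 0.0522%). A library from outside the series or a mixture was not tested, nor was a biological explanation, since both scramble libraries belong to the same group.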

How the results depend on the processing

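TMM, limma, DESeq2, matching on input and matching on nearest bins were chosen after seeing the data. The bound bins numbered 1042 to 1269 under the 5 alternatives of counting, scaling, fold and artefacts, with 1030 of the main bins shared at 1 read per position, and 1704 and 2112 from a single replicate, which asks for less. For 5mC, 0 bins were called under each alternative except without scramble replicate 1 (leaving out each library gave 0 to 37) and with TMM factors, which called 1 bin, on chromosome 7 from 97590001 to 97591000; the cause was not tested. The difference of 5mC at bound bins ran from -0.12 to 0.091 when 1 library was left out. In 2 kb bins it was -0.088 and matched on input -0.11, with camera p = 0.0214 and p = 0.0119 at the preset correlation but p = 0.393 and p = 0.282 at an estimated correlation. It was 0.022 with a pseudocount of 0.1, where the direction turned; the causes were not tested. The scramble and knockdown libraries share only replicate numbers, and their replicate deviations had a correlation of -0.03 across bins. With the replicate block edgeR called 0 bins and the difference at bound bins stayed at -0.01 (camera p = 0.642 at the preset correlation), so the paired fit changed no call.

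The lower 5hmC at bound bins kept its direction under each alternative. Its median was -0.41 with a pseudocount of 0.1, which shrinks low bins less, and relative to matched bins it was -0.45 with that pseudocount, -0.22 with 10 kb scaling and -0.22 against the nearest unbound bins. Counts of 5hmC bins also moved: 15718 higher with 10 kb scaling, and 5681, 24746 and 40390 lower with 2 kb bins, a pseudocount of 0.1 and a log2 limit of 0.58, the last more than the 33141 higher. The triptolide median was -0.087 with 10 kb scaling, and relative to matched bins -0.19 with a pseudocount of 0.1. Of 165 values of named bins under alternatives, 152 were the same, 0 reversed, 11 ChIP values moved and 2 5mC bins passed the threshold. GC correction and narrower promoters were not run, for want of a genome and annotation of the build. Depth limits the caller to strong sites: 9% of simulated 4-fold bins were found.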

Other observations

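5hmC was sparse on chromosome X. Its log2 share of the reads on chromosomes 1 to 19 and X, relative to input, counted over all bins, was -1.14 in the 5hmC scramble library and -0.85 in the knockdown library. In the 5mC libraries it was -0.19 and 0.09 with scramble and -0.30 and -0.36 with knockdown, and in the Lin28A ChIP replicates 0.02 and 0.26. Without the artefact bins these values were -0.22, 0.08, -0.32, -0.40, 0.02 and 0.26. Leaving out bins without input reads as well made them -0.43, -0.17, -0.53, -0.60, -0.19 and 0.02, so the direction turned in scramble replicate 2 and ChIP replicate 1. Such bins hold 17.7% of the chromosome X reads of scramble replicate 2 and 2.29% of its other reads, and 0 input reads by definition, so leaving them out lowers the share on X. Chromosomes 11, 4 and 17 had the largest shares of 5hmC in the scramble library, with log2 values of 0.36, 0.26 and 0.25, and 0.23, 0.15 and 0.17 in the knockdown library.

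At the 38103 bins above input in both 5hmC libraries, 5mC stood at 1.499 and 1.30 relative to input with scramble and at 1.80 and 2.14 with knockdown. The Lin28A ChIP replicates stood at 1.22 and 1.05 there, the drug control at 0.954 and triptolide at 0.959. At the 42318 bins above input in the scramble 5hmC library only, the 5mC values were 1.24, 1.11, 1.40 and 1.56, and ChIP replicate 1, at 1.16, stood above 5mC scramble replicate 2. The input that selected these bins is also the denominator, so values near 1 carry little weight. Lin28A-bound bins lay near each other more often than random bins of the same input count. For 14.1% the nearest other bound bin was not adjoining and lay within 50 kb, against a median of 6.23% and at most 8.11% in 100 random draws. Bins with an adjoining bound bin counted as having none. The draws were not matched on chromosome, over which bound bins were uneven.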
